A study of Homo sapiens with 4 samples.

How the data were processed

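The data are 4 single-cell RNA libraries of the MSTO-211H mesothelioma line, 1 for each of Control, Radiation, Drug and Drug_Radiation, taken 48 h after irradiation with 4 Gy in the irradiated groups and after 10 µM QTP in the treated ones. Per the labels, the libraries were made with a PIPseq V T2 3-prime kit, while another label text names a different platform, so the kit is not settled. The values used were raw UMI counts per gene and cell barcode as deposited by the authors, with no normalization. Per the submitters' processing notes, hg38 and Seurat 4.3.3 were used, with no role given for either. The aligner, the counting program, the strand counted, the annotation and the way barcodes were called are not given in the sources used here. The lowest total per barcode was 1009 UMIs in Control, 1592 in Radiation, 6427 in Drug and 6244 in Drug_Radiation, so barcodes had been filtered before, at levels that differed between libraries. Of 37468 features, 34472 (92.0%) were in GENCODE 29, which gave gene types and positions.

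Cells with at least 500 UMIs and 300 genes and under 20% mitochondrial UMIs were kept. This kept 3183 of 3184 barcodes deposited for Control, 2425 of 2428 for Radiation, 3802 of 3806 for Drug and 6990 of 7006 for Drug_Radiation, and every barcode left out was above the mitochondrial limit. The median number of genes per cell was 920, 1761, 4409 and 3954. Scrublet marked 0, 6, 1 and 0 cells, under 0.5% of each library, so it did not work as a doublet caller here and no cell was removed as a doublet. UMIs were summed over the cells of a library and scaled to its nuclear-encoded total as CPM, and ratios were taken as log2 of CPM plus 1. Intervals at 95% are exact Poisson intervals for CPM, exact conditional binomial intervals for ratios and exact Clopper-Pearson intervals for shares of cells. They and the floor of 3 counts used for a count of 0 cover counting error only. Intervals for ratios leave out the added 1 CPM, so for genes of low CPM they are not centred on the printed ratio.

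With 1 library per group no test across genes was made. An additive model over the crossed design was not fitted, since its error would hold any way in which QTP and radiation act together. Genes with at least 20 CPM in a compared library were counted by a fixed size of 2-fold either way. The comparisons were Radiation against Control, Drug_Radiation against Drug, Drug against Control, Drug_Radiation against Radiation and Drug_Radiation against Control, with the difference of the radiation ratios. The named genes were chosen by a rule. For QTP and for radiation these were the 12 highest and 12 lowest by the smaller absolute log2 ratio of both arms where the sign was the same. For the combination they were the 10 highest and 10 lowest, and for the difference the 6 highest and 6 lowest. Mitochondrially encoded genes, ribosomal protein genes, sex-linked marker genes and clone names were left out. A set of stress, division, sterol and marker genes and the dopamine receptors was named in every comparison, and up to 4 examples were taken from each gene list. RPSAP58, RPS27A, RPS27AP5, LINC00486 and the genes with opposite signs in both arms were named after their values were seen.

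The 29 gene lists were written from general knowledge of the processes they name. Members had at least 5 CPM and a list needed 5 members. Each median was set against 10000 random lists matched in 20 bins of expression. A named copy was a gene whose symbol is that of another gene followed by P and a number, unless RefSeq gives it as protein-coding. For pairs and for the alternative without copies both had to be counted in the files, and for the lipid lists a pseudogene in GENCODE 29 or RefSeq sufficed. Spreads over pairs and over list members were taken from 10000 draws with replacement. For shares of cells, each cell was thinned to 1000 UMIs. Phase classes used S and G2 and M genes at 1% of UMIs or more. Clusters were made by the Leiden method at resolution 0.5 from 2000 variable genes, 30 principal components and 15 neighbours, with seed 0.

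The method was tested on simulated data with 200 changed genes per comparison. All 3-fold and 4-fold changes and none of the 1.5-fold ones passed the 2-fold size, and 0 unchanged genes did. Intervals held the simulated value for 95.6% of genes for radiation without QTP (4544 genes), 94.9% for radiation with QTP (5306), 95.5% for QTP without radiation (4953), 94.8% for QTP with radiation (4881) and 94.8% for the combination (4817). Of 100 random lists, 4, 4, 10, 4 and 9 lay outside the limits, and all 100 lists shifted by 0.5 lay above them, on 9764, 10305, 10353, 10158 and 10227 genes. The simulation holds counting error and no variation between libraries.

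Alternatives to these choices were all barcodes, a stricter cell filter of 1000 UMIs, 500 genes and 10% mitochondrial UMIs, removal of the cells marked by Scrublet, TMM scaling by edgeR, median-of-ratios scaling by DESeq2, equal weight per cell, thinning of all cells, pseudocounts of 0.1 and 5 CPM, and gene minimums of 5 and 50 CPM. Thinning to 500 and 2000 UMIs, no thinning, class limits of 0.5% and 2% and resolutions of 0.3 and 1 were tried for cells. Cells of 6500 to 15000 UMIs, protein-coding genes with no named copy and the libraries without Control were added after seeing the data. edgeR and DESeq2 gave scaling factors alone, and the TMM factors were 0.886, 0.939, 1.17 and 1.03. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.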

Results

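Single-cell RNA libraries were made from MSTO-211H, a human pleural mesothelioma cell line, grown as suspended cells in serum-free medium with growth factors. The culture is described in the labels as mesothelioma-initiating cells. The 4 libraries formed a crossed design with 1 library per group: Control, Radiation (4 Gy), Drug (10 µM QTP, a compound the series title places under dopamine receptor inhibition) and Drug_Radiation (both). Cells were collected 48 h after irradiation. Control held 3183 cells with 9249567 UMIs in all and a median of 2318 UMIs per cell. Radiation held 2425 cells with 14859709 UMIs and a median of 5299. Drug held 3802 cells with 90903552 UMIs and a median of 20405. Drug_Radiation held 6990 cells with 149368293 UMIs and a median of 18024.5. With 1 library per group no difference had a replicate check, no test was made across genes, and the 95% intervals cover counting error only. Cells of the libraries with QTP carried several times more UMIs than cells of the others, so QTP, depth and any library batch that went with it cannot be told apart by the design.

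Levels are UMI counts scaled to the nuclear-encoded total of each library (CPM), and differences are log2 ratios of CPM plus 1. The intervals of these ratios leave out the added 1 CPM. Among genes with at least 20 CPM the median log2 ratio was 0.18 for radiation without QTP, -0.18 for radiation with QTP, 0.50 for QTP without radiation, 0.13 for QTP with radiation and 0.33 for the combination against Control. Gene lists hold genes with at least 5 CPM, whose medians were 0.12, -0.14, 0.47, 0.19 and 0.33 in the same order. The median of a list minus this median of all genes is its relative median. A list stood apart when its median lay outside the central 95% of 10000 random lists of equal size and similar expression, as a description of the libraries and not as a test. TMM scaling ended none of these calls.

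The radiation comparisons asked how cells 48 h after 4 Gy differed from cells that were not irradiated, without QTP (Radiation against Control) and with it (Drug_Radiation against Drug). In both, p53 target genes were higher and genes of the cell division cycle were lower relative to all genes. Among cells of closer depth (6500 to 15000 UMIs, a range chosen after seeing the data) this held with QTP. Without QTP none of the p53, S phase and G2 and M phase lists stood apart there. CDKN1A had a log2 ratio of 0.68 without QTP in that range, as given below. CDKN1A, the cell cycle inhibitor p21, had 172 CPM in Control and 393 CPM in Radiation, a log2 ratio of 1.19 (1.11 to 1.27). With QTP it had 359 CPM without and 478 CPM with radiation, a log2 ratio of 0.41 (0.39 to 0.43). MDM2, the ubiquitin ligase that limits p53, had log2 ratios of 0.59 (0.45 to 0.74) and 0.54 (0.51 to 0.59). GDF15, a secreted stress cytokine, had 1.05 and 0.53. TOP2A, the topoisomerase of dividing cells, had -0.69 (-0.86 to -0.54) and -0.77 (-0.84 to -0.73), and the proliferation marker MKI67 had -1.08 and -0.87.

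Of 25 p53 targets measured, 18 lay above the median of all genes in both radiation comparisons and 0 lay below it in both. Their relative median was 0.35 without QTP (percentile 99.98) and 0.30 with QTP (percentile 100). BTG2, an antiproliferative p53 target, had a log2 ratio of 1.28 without QTP, while PPM1D had -0.26 and SESN1 -0.09. With QTP the largest ratios on the list were 0.86 for the kinase PLK3 and 0.68 for BBC3, which encodes the death protein PUMA, and the smallest were -0.24 for XPC and -0.13 for FDXR. Of 51 G2 and M phase genes, 44 lay below the median of all genes in both comparisons, with relative medians of -0.50 and -0.60 (percentile 0 in both). CENPF, a kinetochore protein, had -0.80 and -1.11, and NUF2, of the same structure, had -1.17 with QTP. RANGAP1 was an exception with 1.31 without QTP and -0.10 with it, and TUBB4B had 0.50 without QTP. S phase genes had relative medians of -0.23 (percentile 0.26) and -0.32 (percentile 0), with 22 of 35 below the median of all genes in both. TYMS, which makes thymidylate, had -1.15 without QTP but 0.11 with it. RAD51AP1, a recombination factor, had -1.19 and PRIM1, a primase subunit, -0.85 with QTP. Homologous recombination and Fanconi genes had relative medians of -0.46 (percentile 0.64) and -0.30 (percentile 0.02), BRCA2 having -0.74 without QTP and FANCI -0.53 and -0.72.

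No gene was 2-fold higher, or 2-fold lower, in both radiation comparisons among 5673 measured. Independent lists would share 0.310 and 0.0518 genes. Left without the Control library, the single remaining comparison, with QTP, had 15 genes 2-fold higher and 7 lower. Without QTP, 105 genes were 2-fold higher and 42 lower of 4818, and TMM scaling, which scales libraries by their typical gene, gave 73 and 58. With QTP it gave 26 higher and 0 lower. Across genes the radiation ratios of both arms had a Pearson correlation of -0.0810 and a Spearman correlation of -0.0564, where genes are not independent replicates.

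The genes highest with radiation in both arms, by the smaller of the paired ratios, were led by SYVN1, a ubiquitin ligase of the endoplasmic reticulum (7.93 CPM in Control, 16.8 in Radiation, 35.3 in Drug and 57.1 in Drug_Radiation). After it came MDM2, GDF15, the tetraspanin TSPAN9 (0.50 and 0.52), PCBP4, an RNA-binding p53 target (0.79 and 0.48), PTOV1 (0.47 and 0.53) and NIBAN2 (0.42 and 0.61). The metallothionein MT2A had 0.45 and 0.41, the collagen chain COL6A1 0.92 and 0.41, FLII 0.97 and 0.40, and the procollagen protease BMP1 0.48 and 0.39. The genes lowest in both arms were the phosphatase CDKN3 (-0.90 and -1.09), the centromere proteins CENPN (-0.87 without QTP) and CENPW (-0.87 and -0.77), PRR11 (-0.83 and -0.85) and the PCNA-binding factor PCLAF (-0.75 and -1.06). PTTG1, or securin, had -0.63 and -0.93, DUT, which clears dUTP, -0.63 and -0.71, UBE2T of the Fanconi pathway -0.65 and -0.58, CKS2 -0.57 and -0.59, and the mitotic kinase AURKA -0.56 and -0.60. SRD5A2, a steroid reductase, had -1.29 and -0.86. Among cells of 6500 to 15000 UMIs, ratios without QTP turned for MT2A (-0.03), BMP1 (-0.02), PTTG1 (0.06) and UBE2T (0.12). They came near 0 for CDKN3 (-0.0050), AURKA (-0.04) and PRR11 (-0.07), while ratios with QTP ran from 0.30 (MDM2) to 0.77 (PCBP4) and from -1.36 (PCLAF) to -0.55 (UBE2T). CDKN1A lies on chromosome 6 from 36676460 to 36687339, MDM2 on chromosome 12 from 68808176 to 68850686 and TOP2A on chromosome 17 from 40388516 to 40417950 of GRCh38.

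Several other lists stood apart with radiation in 1 or both arms. Radiation ratios without QTP share the Control library with the QTP ratios without radiation and the combination. Summed over members, the integrated stress response had 1235 CPM in Control against 2101, 2616 and 2379 in Radiation, Drug and Drug_Radiation. Hypoxia and glycolysis genes had 10174 against 13046, 14228 and 13603 CPM, and lysosome genes 3136 against 4754, 5121 and 5180. A trait of Control alone cannot be told apart from a response to treatment in these lists. Summed p53 targets were lowest in Control too (1144 CPM against 1820, 1867 and 2185), as was CDKN1A, so this limit holds for their levels against Control. As a list, however, p53 targets did not stand apart in Drug against Control (relative median 0.05). Radiation with QTP does not use Control. The integrated stress response had a relative median of 0.45 (percentile 100) without QTP and -0.04 (percentile 40.6) with it, STC2 having 1.31 and 0.08 and PPP1R15A 1.19 without QTP. Hypoxia and glycolysis genes had 0.39 (percentile 100) and -0.03 (percentile 25.8), with 1.64 for NDRG1 and 1.38 for the secreted lipase inhibitor ANGPTL4 without QTP. Endoplasmic reticulum chaperones had 0.35 (percentile 99.95) and 0.11 (percentile 93.5), and the chaperone HSPA5 had log2 ratios of 0.77 and -0.05. Nuclear-encoded oxidative phosphorylation genes had -0.31 (percentile 0) and -0.00 (percentile 13.5), with 0.61 for SDHA and -1.27 for CYC1 without QTP. Fatty acid synthesis genes had -0.32 (percentile 0.17) and -0.04 (percentile 50.2), FASN having -0.58 without QTP and 0.62 with it. Lysosome genes stood apart in both arms, at 0.36 (percentile 99.99) and 0.14 (percentile 99.98), with 1.52 for the glucosidase GAA and 1.11 for the protease CTSD without QTP. Mesenchymal and matrix genes had 0.18 (percentile 96.6) and 0.26 (percentile 100), and MMP2, a gelatinase, had 0.51 with QTP. Cholesterol synthesis and uptake genes had -0.07 (percentile 10.8) and -0.26 (percentile 0), SQLE having 0.16 and -0.71. Cytosolic ribosomal protein genes had -0.23 (percentile 3.29) and 0.31 (percentile 100).

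The libraries without QTP also differed in depth, and the comparison was repeated among cells of 6500 to 15000 UMIs. Control had 173 cells in that range, against 770, 1023 and 2533 in Radiation, Drug and Drug_Radiation. Median depth there was 7775 UMIs in Control, 8566 in Radiation, 10833 in Drug and 11462 in Drug_Radiation, so depth was closer but not equal. The range took cells deeper than the medians of Control and Radiation and shallower than those of Drug and Drug_Radiation. Cells in which S or G2 and M phase genes made up at least 1% of UMIs changed in share there. Shares went from 3.30% to 3.47% in Control, 2.68% to 5.19% in Radiation, 4.39% to 2.25% in Drug and 1.30% to 0.790% in Drug_Radiation. Values of division lists in this range may thus come from the cells it took. Without QTP the p53 targets then had a relative median of 0.16 (percentile 92.2), S phase genes 0.05 (percentile 74.8) and G2 and M phase genes -0.08 (percentile 16.3), so none of these lists stood apart. In that range homologous recombination and Fanconi genes (-0.33), fatty acid synthesis (-0.06), lysosome genes (0.12), the integrated stress response (0.10) and endoplasmic reticulum chaperones (0.06) did not stand apart without QTP either. Hypoxia and glycolysis genes (0.30, percentile 99.99) and oxidative phosphorylation genes (-0.18, percentile 0.01) still stood apart without QTP. With QTP the p53 targets (0.32), S phase genes (-0.26), G2 and M phase genes (-0.52), recombination genes (-0.42), cholesterol genes (-0.35), lysosome genes (0.26) and matrix genes (0.35) stood apart in that range as well. Cytosolic heat shock genes (0.26) without QTP, and NRF2 targets (0.20), fatty acid genes (-0.14), apoptosis regulators (-0.13) and oxidative phosphorylation genes (-0.0037) with QTP, stood apart in that range but not in all cells. CDKN1A had log2 ratios of 0.68 and 0.66 there. In all cells thinned to 1000 UMIs, S phase genes (-0.11, percentile 14.9) and recombination genes (-0.43, percentile 7.11) did not stand apart without QTP. The p53 targets (0.40), G2 and M phase genes (-0.59) and fatty acid synthesis (-0.32) did. So did lysosome genes (0.44), the integrated stress response (0.62) and chaperones (0.38). Thinning evens out UMIs per cell but keeps the expected make-up of each cell. It therefore could not show whether depth accounts for these calls.

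**Figure D1:**
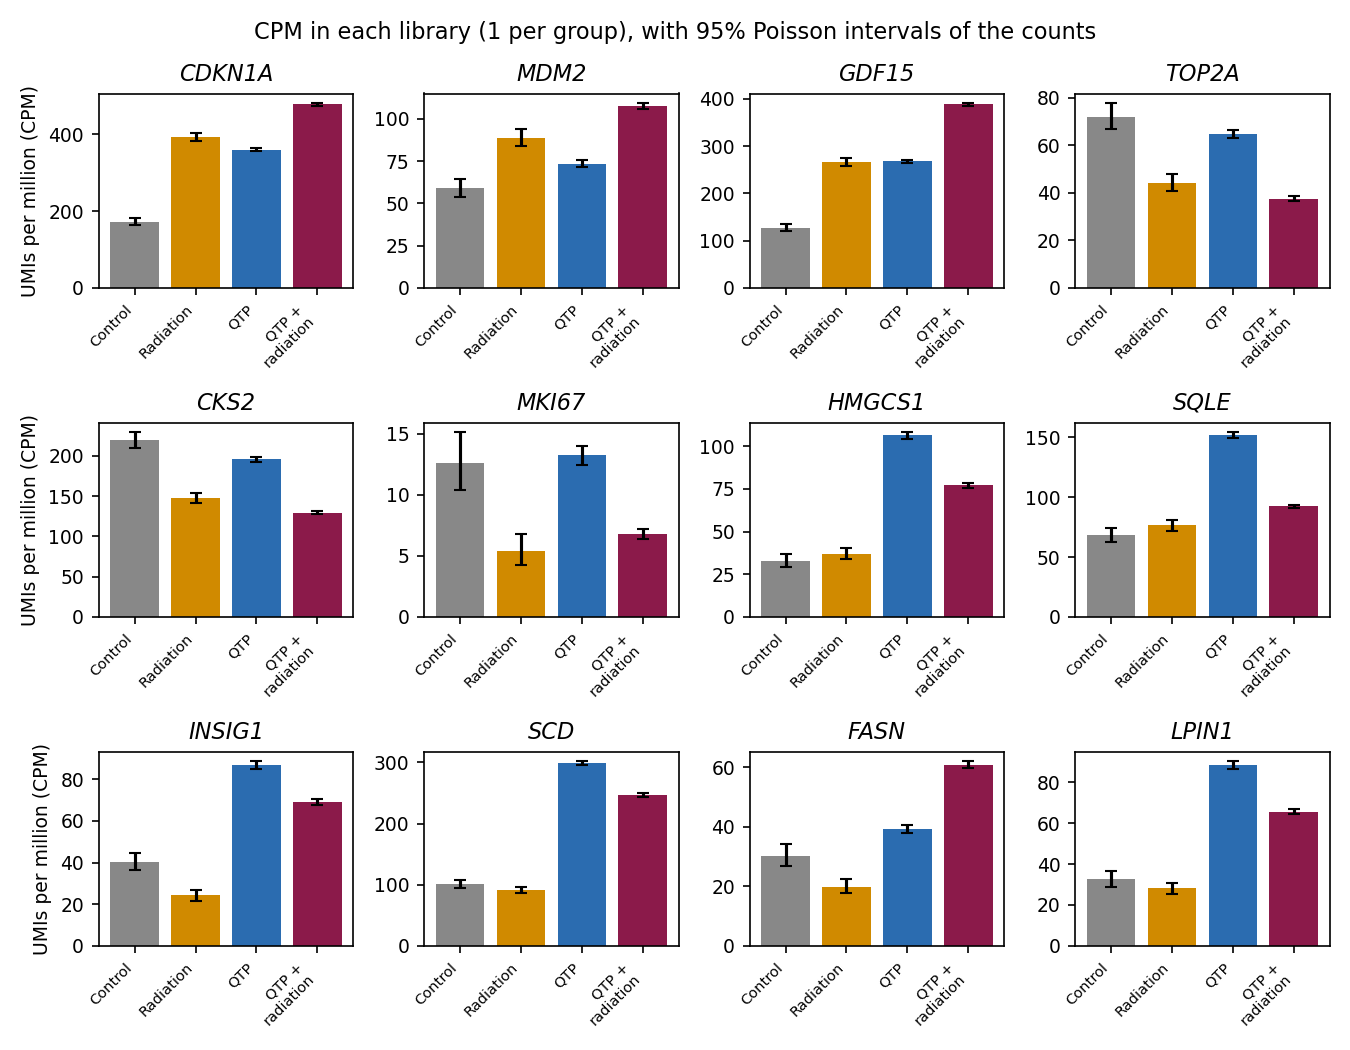
Level of 12 genes in each of the 4 libraries in CPM, from a linear axis that starts at 0, as bars with 95% Poisson intervals that cover counting error only, 1 library per group. CDKN1A was lowest in Control at 172 CPM, and SCD was higher in the libraries with QTP (299 and 247 CPM) than in the others (101 and 90.8 CPM).

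The QTP comparisons asked how cells treated with the compound differed from untreated cells, without radiation (Drug against Control) and with it (Drug_Radiation against Radiation). These ratios share no library. In both, genes that make and take up cholesterol and fatty acids were higher. HMGCS1, an early enzyme of sterol synthesis, had 32.6 CPM in Control and 106 CPM in Drug, a log2 ratio of 1.67 (1.53 to 1.88). With radiation it had 36.9 and 77.2 CPM, a log2 ratio of 1.04 (0.94 to 1.19). SCD, the stearoyl-CoA desaturase, had 1.56 (1.48 to 1.67) and 1.43 (1.36 to 1.52).

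All 24 cholesterol synthesis and uptake genes measured lay above the median of all genes in both QTP comparisons. Their relative median was 0.63 without radiation and 0.42 with it (percentile 100 in both). Without radiation the largest ratios were 2.20 for DHCR7, the last enzyme of the pathway, and 1.99 for MVD, and the smallest 0.61 for MVK and 0.74 for TM7SF2. With radiation INSIG1, a sterol sensor, had the largest ratio, 1.47, and HSD17B7 (0.26) and SQLE (0.27) the smallest. Of 13 fatty acid synthesis genes, 9 lay above the median of all genes in both, with relative medians of 0.38 (percentile 99.82) and 0.71 (percentile 100). ACLY, which makes cytosolic acetyl-CoA, had 1.67 without radiation, FASN, the fatty acid synthase, 1.56 with it, and LPIN1, a phosphatidate phosphatase, 1.41 and 1.19. ACACA (0.17 without radiation) and ELOVL5 (0.08 with it) had the smallest ratios. Among cells of 6500 to 15000 UMIs the relative medians were 0.81 and 0.35 for the cholesterol list and 0.79 in both arms for the fatty acid list. HMGCS1 lies on chromosome 5 from 43289395 to 43313512 and SCD on chromosome 10 from 100347124 to 100364834.

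Among 5673 genes, 19 were 2-fold higher and 97 were 2-fold lower with QTP in both arms, where independent lists would share 5.11 and 2.36. TMM scaling gave 12 higher, cells of 6500 to 15000 UMIs gave 97 higher, and protein-coding genes with no named copy gave 62 lower. Left without the Control library, the single remaining comparison had 60 higher and 84 lower. Across genes the QTP ratios of both arms had a Pearson correlation of 0.577 and a Spearman correlation of 0.192, where genes are not independent replicates. Among cells of 6500 to 15000 UMIs the Spearman correlation was 0.569. Without radiation 477 genes were 2-fold higher and 130 lower of 5546, but TMM scaling gave 63 higher and 179 lower. With radiation 60 were higher and 84 lower of 5239, and TMM scaling gave 38 and 93.

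The genes highest with QTP in both arms were led by ARF5, a small GTPase of vesicle transport, with 1.23 and 0.837 CPM in Control and Radiation and 53.3 and 67.7 CPM in Drug and Drug_Radiation. Its log2 ratios were 4.61 and 5.22, which depend on the added 1 CPM at levels as low as those without QTP. Whether reads of ARF5 were placed differently between libraries was not tested. MYEOV had 3.79 and 4.48, but rested on 1 UMI in Control and 4 in Radiation, so that the counting interval of the ratio without radiation ran from 4.53 to 12.31 before the added 1 CPM. SYVN1 had 2.02 and 1.70, CLVS1 1.60 and 2.04, SBF2 1.35 and 1.51, the phosphohistidine phosphatase PHPT1 1.56 and 1.24, and MKKS 1.47 and 1.22. DDTL (3.43 and 4.18), HNRNPA1L2 (2.29 in both) and POM121C (1.32 and 1.22) are near copies of DDT, HNRNPA1 and POM121, so reads may have been split between them and their values are uncertain. The lowest genes were led by others. NGB, or neuroglobin, had 2944 and 1406 CPM in Control and Radiation and 177 and 134 CPM in Drug and Drug_Radiation, log2 ratios of -4.05 and -3.38. ATP6V0D2, a proton pump subunit, had -4.87 and -3.92, the steroid reductases AKR1D1 -5.18 and -3.54 and SRD5A2 -2.86 and -2.44, and MAMDC2 -3.77 and -2.95. PDZD2 had -3.75 and -2.91, PLEKHA6 -3.43 and -2.75, TMIGD3 -3.81 and -2.67, the reelin adaptor DAB1 -2.90 and -2.44, the adaptor GRAP2 -2.62 and -2.38, and BCL2L14 -2.42 and -2.32. These lowest genes lie among 46 genes at least 4-fold lower in both arms. The median of the 46 against all genes was -3.94 and -2.69 in all cells. Among cells of 6500 to 15000 UMIs it was -2.87 and -2.12, a smaller difference. ADGRL3-AS1 (-4.47 and -3.70) is an antisense gene, and the strand used in counting is not given in the sources used here, so its value is uncertain. NGB lies on chromosome 14 from 77265483 to 77271312 and ARF5 on chromosome 7 from 127588345 to 127591705.

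**Figure D2:**
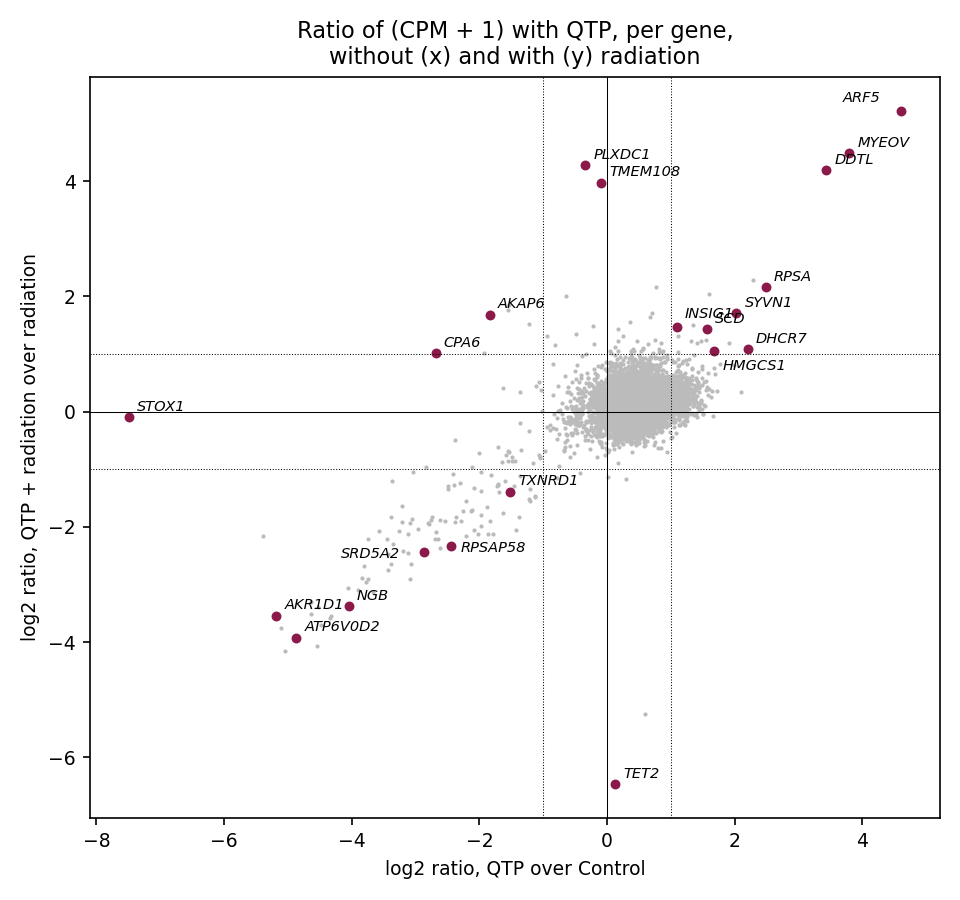
Log2 ratio of each gene for QTP without radiation (horizontal axis) against QTP with radiation (vertical axis), 1 point per gene among 5673 genes, with 2-fold limits as dotted lines and named genes in dark red. The 97 genes 2-fold lower in both arms lie at the lower left, and ARF5 lies at the upper right with 4.61 and 5.22.

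Other lists were higher with QTP in 1 or both arms. The integrated stress response had relative medians of 0.61 (percentile 100) and 0.16 (percentile 99.84), with 12 of 21 above the median of all genes in both. PHGDH, the entry enzyme of serine synthesis, had 1.65 without radiation, the cystine carrier SLC7A11 0.92 with it, the stress factor DDIT3 1.14 and 0.54, and ATF3 0.89 and 0.14. In the depth range the list had 0.25 and 0.08, and with radiation it no longer stood apart. Hypoxia and glycolysis genes had 0.33 (percentile 100) and -0.09 (percentile 63.1), with 2.10 for ANGPTL4 and 2.06 for the peptide ADM without radiation. Lysosome genes had 0.30 (percentile 100) and 0.06 (percentile 99.74), CTSD having 1.41 and the cholesterol exporter NPC1 1.34 without radiation, but in the depth range the list had -0.10 without radiation. NF-kB and secretory inflammatory genes had 0.21 (percentile 98.0) and 0.17 (percentile 96.0), ICAM1 having 1.51 and MMP1 -2.81 without radiation, and in the depth range 0.14 (percentile 82.0) without radiation. NRF2 targets had -0.04 and 0.16 (percentile 99.47), with -1.52 and -1.39 for the thioredoxin reductase TXNRD1, and in the depth range 0.07 (percentile 94.5) with radiation.

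Immediate early genes had -0.28 (percentile 0.56) without radiation and 0.24 (percentile 99.56) with it, but in the depth range -0.10 and 0.17, where they did not stand apart. YAP and TEAD targets had -0.09 (percentile 7.33) and 0.22 (percentile 99.94), CRIM1 having 0.81 with radiation, and in the depth range 0.24 and 0.41, where they stood apart in both. Stem cell and initiating cell markers had -0.06 (percentile 31.5) and 0.18 (percentile 98.1), NOTCH1 having 0.82 and MYC -0.69 with radiation, and -0.02 (percentile 65.9) in the depth range with radiation. CD44, a surface marker on that list, had 0.61 and -0.08. Oxidative phosphorylation genes had -0.27 (percentile 38.1) and 0.07 (percentile 100), and in the depth range -0.03 with radiation, still above random lists (percentile 99.95). Cytosolic ribosomal protein genes lay below the median of all genes in both arms for 31 of 35 members, with relative medians of -0.86 (percentile 0) and -0.30 (percentile 3.81). RPL27 had -0.89 and RPL34 -0.79 without radiation. In the depth range the list had -0.44 (percentile 0.70) and -0.07, the latter above random lists (percentile 99.3). RPSA had 2.48 and 2.16, but its processed copy RPSAP58 had -2.45 and -2.33, so the value of RPSA is uncertain.

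Of the cell cycle lists, G2 and M phase genes were lower with QTP relative to all genes in both arms, with relative medians of -0.16 (percentile 0.20) and -0.25 (percentile 0). S phase genes had -0.10 (percentile 5.67) without radiation, where they did not stand apart, and -0.27 (percentile 0) with it. Without radiation their own median log2 ratios were 0.30 and 0.37, above 0 but below the 0.47 of all genes, and with TMM scaling -0.07 and -0.03. The G2 and M phase list did not stand apart without radiation in cells thinned to 1000 UMIs (percentile 4.83). HMGB2, a chromatin protein of dividing cells, had -0.79 with radiation and UBE2C -0.22 without it. In the depth range the G2 and M phase list had -0.39 and -0.79 and the S phase list -0.33 and -0.64. As given above, cells with division genes at 1% of UMIs were more frequent there in Radiation and less frequent in Drug and Drug_Radiation. Lower values there may thus come from the cells the range took. With radiation, recombination and Fanconi genes (-0.39), inflammatory genes (0.32) and matrix genes (0.28) stood apart in that range but not in all cells. The p53 targets had 0.05 (percentile 64.5) and 0.08 (percentile 95.99), and did not stand apart. CDKN1A had log2 ratios of 1.06 and 0.28 and MDM2 of 0.32 and 0.27, but in the depth range CDKN1A had -0.05 and -0.07.

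The combination comparison asked how cells given both treatments differed from Control. Lipid synthesis genes and p53 targets were higher and division genes were lower. GDF15 had 128 CPM in Control and 389 CPM in Drug_Radiation, a log2 ratio of 1.60 (1.52 to 1.69), and CDKN1A had 1.47 (1.40 to 1.55). Among cells of 6500 to 15000 UMIs CDKN1A had 0.61, below 2-fold. HMGB2 had -1.18, TOP2A -0.92 (-1.06 to -0.82) and NUF2 -1.01. DHCR7 had 1.82 (1.69 to 2.03).

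The lowest relative median was that of G2 and M phase genes, -0.76 (percentile 0), where 30 of 48 lay at least 1.5-fold below the median of all genes. S phase genes had -0.40 (percentile 0). Recombination and Fanconi genes had -0.62 (percentile 0.04), but -0.16 (percentile 20.7) in cells thinned to 1000 UMIs, where they did not stand apart. The p53 targets had 0.29 (percentile 99.94), with 23 of 25 above the median of all genes, and in the depth range 0.15 (percentile 97.0), where they did not stand apart. Cholesterol genes had 0.32 (percentile 99.98), with LSS at 1.55, and fatty acid genes 0.47 (percentile 99.99), with ACLY at 1.44. The integrated stress response had 0.53 (percentile 100), lysosome genes 0.43 (percentile 100), hypoxia and glycolysis genes 0.28 (percentile 100) and matrix genes 0.28 (percentile 99.91), where MMP2 had 1.32 and COL6A1 1.26. In the depth range the integrated stress response had 0.24 and lysosome genes 0.11, while S phase genes had -0.62. Ribosomal protein genes had -0.56 (percentile 0.01), but -0.22 (percentile 48.0) in the depth range. Chaperones (0.12), immediate early genes (0.05), NRF2 targets (0.08), interferon genes (0.10), inflammatory genes (0.21), oxidative phosphorylation genes (-0.23), stem cell markers (0.04) and YAP and TEAD targets (0.09) did not stand apart. Of these, YAP and TEAD targets stood apart in the depth range (0.21, percentile 99.1), and inflammatory genes with TMM scaling (0.23, percentile 97.7) and in thinned cells (0.47, percentile 99.94).

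With both treatments 281 of 5243 genes were 2-fold higher and 127 were 2-fold lower than in Control. TMM scaling gave 105 and 154 and median-of-ratios scaling 80 and 163, so the larger direction depended on the scaling. The highest genes were ARF5 (4.94), MYEOV (4.68), DDTL (4.20), PLXDC1 (4.01), TMEM108 (3.67), SYVN1 (2.70), HNRNPA1L2 (2.54), CLVS1 (1.92), DHCR7 (1.82) and ARFGAP1, a regulator of vesicle coats (1.80). The lowest were STOX1 (-7.34), ATP6V0D2 (-5.17), AKR1D1 (-4.74), NGB (-4.45), ADGRL3-AS1 (-4.32), TMIGD3 (-4.07), the thyroid hormone receptor THRB (-4.03), DSCAML1 (-3.99), PDZD2 (-3.92) and MAMDC2 (-3.75). MSLN, which encodes mesothelin, had 0.70, and VIM, or vimentin, 0.08.

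**Figure D3:**
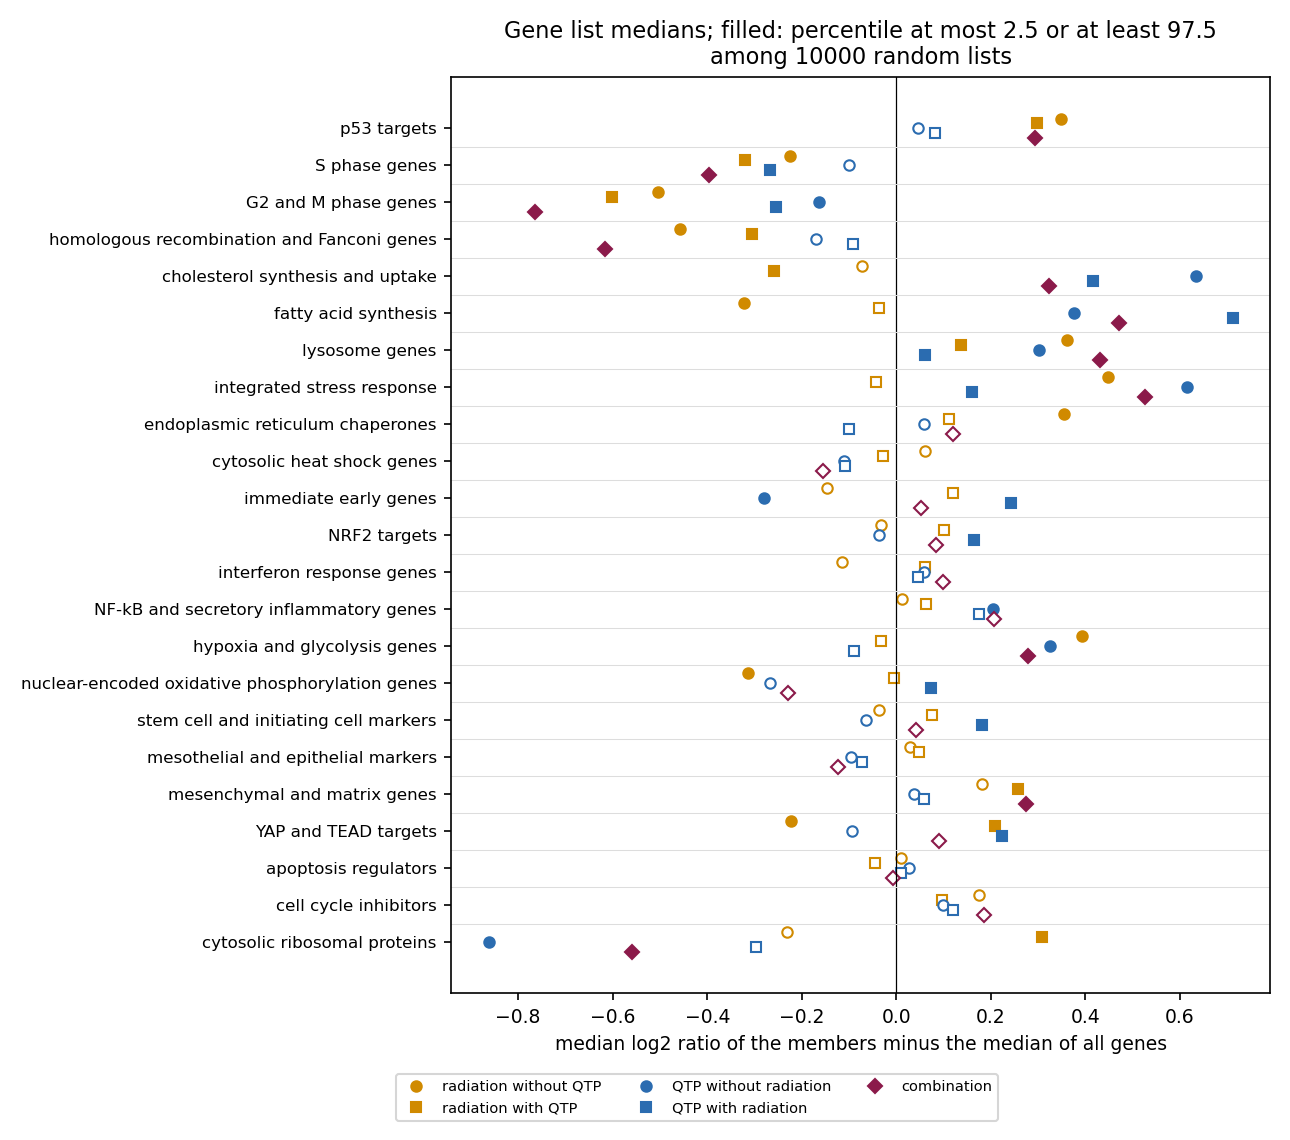
Median log2 ratio of each gene list minus the median of all genes, on a log2 axis, with 1 symbol per comparison and filled symbols for lists outside the central 95% of random lists. G2 and M phase genes lie below 0 in all 5 comparisons, and cholesterol genes lie above 0 in the QTP and combination comparisons.

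The difference between the radiation ratios with and without QTP asked whether radiation went with other levels where QTP was present. It was not tested, and every library enters it. Several of the largest differences came from a gene seen almost in a single library. STOX1, a transcription factor, had 267 CPM in Control and at most 0.768 CPM elsewhere (difference 7.39). PLXDC1 had 45.6 CPM and TMEM108 48.6 CPM in Drug_Radiation and at most 1.90 and 2.91 CPM elsewhere (differences 4.63 and 4.06). CPA6, a carboxypeptidase, had 3.70, the kinase anchor AKAP6 3.52, and KIF5C-AS1, an antisense gene and so uncertain, 3.39. TET2, a DNA demethylase, had 453 CPM in Radiation and at most 4.60 CPM elsewhere (difference -6.59). ANGPTL4 (-1.77), NUCB1 (-1.75), NDRG1 (-1.65), OS9 (-1.55) and AP5Z1 (-1.54) had radiation ratios from 1.38 to 1.75 without QTP and from -0.38 to 0.07 with it. NUCB1 for example had 25.6 CPM in Control and from 83.4 to 88.6 CPM in the other libraries.

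The hypoxia and integrated stress lists had their lowest summed level in Control, as given above. Their differences thus cannot be told apart from a trait of that library. Hypoxia and glycolysis genes (relative median of the difference -0.56, percentile 0) and the integrated stress response (-0.48, percentile 0.01) had lower radiation ratios with QTP than without. S phase genes had -0.17 (percentile 2.11), but 0.0054 with a minimum of 50 CPM. Ribosomal protein genes (0.64, percentile 100), immediate early genes (0.49, percentile 99.92), stem cell markers (0.41, percentile 99.45), YAP and TEAD targets (0.39, percentile 100), oxidative phosphorylation genes (0.35, percentile 99.78) and fatty acid genes (0.25, percentile 98.7) had higher ones. In the depth range the hypoxia list (-0.28), S phase genes (-0.24) and ribosomal protein genes (0.38) still stood apart, whereas the integrated stress response (-0.10), immediate early genes (0.28), stem cell markers (0.16), YAP and TEAD targets (0.07), oxidative phosphorylation genes (0.13) and fatty acid genes (0.01) did not. The p53 targets had 0.16 (percentile 95.9), G2 and M phase genes -0.05 (percentile 14.5) and cholesterol genes -0.16 (percentile 30.6), but in the depth range they stood apart with 0.23 (percentile 98.8), -0.41 (percentile 0) and -0.38 (percentile 0). Inflammatory genes (0.37), NRF2 targets (0.34), matrix genes (0.31), interferon genes (0.29) and lysosome genes (0.17) stood apart in that range but not in all cells. Lysosome genes had -0.23 (percentile 6.68) in all cells and stood apart the other way in thinned cells (-0.29, percentile 2.24). Endoplasmic reticulum chaperones stood apart in thinned cells (-0.33) but not in all cells (-0.04). In thinned cells the p53 targets (-0.10, percentile 32.7), inflammatory genes (-0.10, percentile 26.1), matrix genes (-0.08), NRF2 targets (0.03) and interferon genes (0.14) did not stand apart. Neither did G2 and M phase genes (-0.14), cholesterol genes (-0.13) and fatty acid genes (0.23, percentile 97.3). Thinning keeps the expected make-up of each cell, so it could not weigh the depth-range values either way. That range was chosen after seeing the data, so no difference was read from it alone.

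Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs. CDKN1A was seen in 12.2% of Control cells (11.0 to 13.3), 29.9% of Radiation, 26.0% of Drug and 32.2% of Drug_Radiation cells. Before thinning the shares were 29.5%, 72.7%, 91.3% and 96.4%, at the median depths given above. SCD was seen in 8.99%, 7.75%, 23.8% and 20.2% of cells, and before thinning in 21.6% of Control, 34.4% of Radiation and 89.3% of Drug_Radiation cells. TOP2A was seen in 5.09%, 3.30%, 4.97% and 2.89%. All cells are of 1 line, so no cell type lacking these genes gave a background, and free RNA remains open. Cells in which S or G2 and M phase genes made up at least 1% of UMIs were 3.30% of Control (2.71 to 3.98), 2.68% of Radiation (2.07 to 3.40), 4.39% of Drug (3.76 to 5.09) and 1.30% of Drug_Radiation (1.05 to 1.60). These classes rested on cells near their limit, 81 of them in Control beside 105 cells in the class. With a limit of 0.5% the shares were 11.7%, 8.70%, 13.6% and 6.34%, and with 2% they were 0.0314%, 0.0412%, 0.342% and 0.0143%. Among cells of 6500 to 15000 UMIs they were 3.47% of Control (6 of 173 cells, 1.28 to 7.40), 5.19% of Radiation (3.74 to 7.01), 2.25% of Drug (1.43 to 3.35) and 0.790% of Drug_Radiation (0.483 to 1.22). The G2 and M phase list took 2006, 1754, 2415 and 1670 CPM, and no rate of cycling was read from these shares alone.

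Lists of other processes did not stand apart with radiation or QTP in all cells. Interferon response genes had relative medians of -0.12 and 0.06 with radiation and 0.06 and 0.05 with QTP. Apoptosis regulators had 0.01 and -0.05 with radiation and 0.03 and 0.01 with QTP, BCL2L1 having 0.80 with radiation without QTP and DIABLO 1.33 with QTP without radiation. Cell cycle inhibitors had 0.18 and 0.10 with radiation and 0.10 and 0.12 with QTP, and CDKN2A had at most 0.894 CPM without QTP but 6.61 and 6.88 CPM with it. Cytosolic heat shock genes had 0.06 and -0.03 with radiation and -0.11 in both QTP comparisons, where HSPA1A and HSPA1B are near copies and uncertain. Mesothelial and epithelial markers had 0.03 and 0.05 with radiation and -0.10 and -0.07 with QTP, KRT8 having 0.66 with radiation without QTP and the calretinin gene CALB2 0.81 with QTP without radiation.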

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

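Of the tests in this part, those on reads shared between genes and their copies across 6 pairs and on sterol and fatty acid genes with no copy were set before their results were seen, apart from their spreads, the rule for what counts as a copy and the split by list, and the other tests were chosen after.

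Some effects went opposite ways in both arms of the design, and these differences were not tested. Immediate early genes had a relative median of -0.28 with QTP without radiation and 0.24 with QTP with radiation. YAP and TEAD targets had -0.22 with radiation without QTP and 0.21 with radiation with QTP. Among cells of 6500 to 15000 UMIs these values were -0.10 and 0.17 for immediate early genes and -0.04 and 0.03 for YAP and TEAD targets, and neither list stood apart in either arm. At least 2-fold apart in opposite directions were 6 genes for QTP, among them AKAP6 (-1.84 and 1.68), CPA6 (-2.69 and 1.02), KIAA0825 (-1.93 and 1.01) and PCBD2 (-1.22 and 1.52), and 4 for radiation, which were AKAP6 (-1.28 and 2.24), CPA6 (-1.17 and 2.53), CSKMT (135 CPM in Control, 66.6 in Radiation, 86.2 in Drug and 271 in Drug_Radiation) and DSCAML1 (-1.84 and 1.39). In mitochondrially encoded genes, which the comparisons do not use, the share of UMIs was 3.55% in Radiation (3.54 to 3.56), 4.08% in Drug (4.07 to 4.08) and 5.20% in Drug_Radiation (5.19 to 5.20), above the 3.26% of Control (3.25 to 3.27).

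A group of 46 genes, with NGB and ATP6V0D2 among them, was at least 4-fold lower with QTP in both arms. It took 2.38% of nuclear UMIs in Control, 1.22% in Radiation, 0.217% in Drug and 0.201% in Drug_Radiation. Per cell it had 66.9, 72.1, 49.7 and 40.8 UMIs in the same order. Between whole libraries the lower share thus came mostly with more UMIs of other genes. At like depth the group itself was lower. The deepest of 10 bins of Control cells had 133 UMIs of it per cell beside 6881 of other genes. The shallowest bin of Drug cells had 24.6 beside 7201. Among cells of 6500 to 15000 UMIs the median of the group was still -2.12 in the arm nearer 0. This argues against fewer UMIs per cell without QTP as the whole cause, within limits. The genes had been picked in the same libraries. Median depth in that range was still 7775 in Control and 8566 in Radiation against 10833 in Drug and 11462 in Drug_Radiation. A set number of UMIs of these genes in every cell was argued against too, since within libraries their UMIs followed the depth of the cell with a lowest slope of 0.58. That slope below 1 means that their share was lower in deeper cells, so depth may still account for part of the difference. A batch that went with QTP cannot be told apart from QTP, because the lowest median depth with QTP was 3.40 times the highest without.

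Sterol and fatty acid synthesis genes were higher with QTP in both arms, 33 of 37 members lying above the median of all genes in both. Among cells of 6500 to 15000 UMIs the lowest relative median of both lists and arms was 0.35 (0.18 to 0.51 over members drawn again). That argues against depth as the whole cause, but not against a part. Depth in that range was closer and not equal, with medians of 7775 (Control), 8566 (Radiation), 10833 (Drug) and 11462 (Drug_Radiation) UMIs. The range also took cells deeper than the median of Control (2318) and shallower than that of Drug (20405). Reads shared with pseudogenes were argued against for the cholesterol list, where the 20 of 24 members with no pseudogene named after them had at least 0.49 (0.35 to 0.69). They stayed open for the fatty acid list, where 10 of 13 such members had 0.33 without radiation (0.0031 to 0.73). A batch that went with QTP cannot be told apart from an effect of QTP, so an effect of the compound on lipid synthesis remains a hypothesis.

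RPSA and its copy RPSAP58 were apart in opposite directions with QTP, and the log2 ratio of their summed CPM was -0.16 in the arm farther from 0, which is consistent with reads shared between them being placed differently in the libraries with QTP. A change in the amount of RPSA RNA was argued against, since the summed ratio was at most 0.0632 of the ratio of RPSA. Over all 6 pairs measured it stayed open whether this was general. Differences within pairs correlated across pairs at 0.943 between the QTP comparisons and at -0.819 between the radiation ones. The RPSA pair that raised the question is 1 of the 6, so the QTP correlation is no separate support. The median difference within pairs was 1.25 and 0.50 for QTP without and with radiation, against 0.54 and 0.25 for radiation without and with QTP, and the smaller QTP value minus the larger radiation value was -0.0344 (-0.26 to 2.76 over pairs drawn again). Of the 2 pairs apart in both arms, with a median summed ratio of 0.129 of the larger single one, RPS27AP5 had at most 8.46 CPM beside at least 3606 CPM of RPS27A, so the sum followed RPS27A whatever RPS27AP5 did and could not show a change in RNA.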

How the results depend on the processing

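The tests among cells of 6500 to 15000 UMIs, of protein-coding genes with no named copy and without the Control library were chosen after seeing the data, and the other alternatives were set before the data were examined. No paired analysis was possible because the groups share fewer than 2 replicate numbers and the results come from no test. The QTP ratios at each radiation level are given side by side.

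With both treatments against Control, the number of genes 2-fold higher (281) stayed between 223 and 321 in 6 of 13 alternatives and the number lower (127) between 86 and 163 in 12 of 13. With QTP in both arms the number higher (19) stayed between 15 and 21 in 8 of 14 and the number lower (97) between 68 and 110 in 12 of 14.

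TMM scaling gave 105 genes higher with both treatments and 12 higher with QTP in both arms, and median-of-ratios scaling 80 and 10, as their factors lower the ratios of the libraries with QTP. Equal weight per cell gave 465 genes higher with both treatments, 2 genes lower with radiation in both arms, and correlations of 0.556 for QTP and -0.0036 for radiation. Cells thinned to 1000 UMIs gave 525, 29 genes higher with QTP in both arms, 3 lower with radiation in both arms, and correlations of 0.491 and -0.0134. A pseudocount of 5 gave 157 genes higher with both treatments and a QTP correlation of 0.557. The cause was not tested for these last 3 settings.

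A minimum of 5 CPM, which admits more genes, gave 510 higher and 227 lower with both treatments, 42 higher and 156 lower with QTP in both arms, and a QTP correlation of 0.511. A minimum of 50 CPM, which admits fewer, gave 123 higher with both treatments and a correlation of 0.671. Under it the difference of the radiation ratios was 0.0054 for S phase genes and -0.19 for immediate early genes, and NRF2 targets had -0.077 with QTP with radiation, all of the opposite sign.

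Cells of 6500 to 15000 UMIs gave 97 genes higher with QTP in both arms. Pearson correlations were 0.628 for QTP and 0.0363 for radiation. Spearman correlations were 0.569 for QTP and 0.119 for radiation, and both radiation values were of the opposite sign. Signs were also opposite for S phase genes with radiation without QTP (0.049), lysosome genes with QTP without radiation (-0.10), and, with QTP with radiation, oxidative phosphorylation genes (-0.029) and stem cell markers (-0.019). The cause was not tested. Protein-coding genes with no named copy, a smaller set, gave 62 lower with QTP in both arms and a correlation of 0.472. Without the Control library 1 arm was left, with 60 genes higher with QTP, and 15 higher and 7 lower with radiation.

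Of the values of lists that stood apart, 714 stayed so under an alternative, 47 did not and 7 reversed. Of these 54, 26 came with cells of 6500 to 15000 UMIs, 12 with a minimum of 50 CPM and 9 with thinned cells. The 714 include values under a minimum of 5 CPM, which lists already had, so none could change there. Use of all barcodes and removal of cells marked by Scrublet altered few cells, so little could change under them. Ratios of the genes named by size, in the comparison that named them, lay within their counting interval 832 times and outside it 560 times. Gene minimums of 5 and 50 CPM leave the ratio of a gene unchanged. Their values among the 832 were therefore fixed in advance and show no stability. Signs of 4 of the ratios of these named genes turned, all with radiation without QTP among cells of 6500 to 15000 UMIs and none of them 2-fold (MT2A -0.03, BMP1 -0.02, PTTG1 0.06 and UBE2T 0.12). Outside this tally, the QTP ratios of CDKN1A (1.06 and 0.28) turned to -0.05 and -0.07 in that range. Shares of cells lay outside it 113 times and within it 23 times. Depth limits the comparisons with Control, which had 173 cells in that range.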

Other observations

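The receptors the compound class is named for were near the limit of detection. DRD1 and DRD5 had 0 UMIs in all 4 libraries, where the floor of 3 counts is 0.335 CPM in Control, 0.209 in Radiation, 0.0344 in Drug and 0.0212 in Drug_Radiation. DRD2 had 0, 0, 17 and 11 UMIs, DRD3 3, 12, 13 and 39, and DRD4 2, 3, 40 and 61. Of the dopamine, serotonin, histamine and adrenergic receptors listed, HRH1 (9.50, 12.9, 15.6 and 13.1 CPM) and HTR1D (from 8.94 CPM in Control to 14.8 CPM in Drug_Radiation) had at least 5 CPM.

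Lists with fewer than 5 members measured are given as single levels in Control, Radiation, Drug and Drug_Radiation. Of cholesterol efflux genes, the sterol-sensing nuclear receptor NR1H2 had 22.9 CPM in Control, 55.3 in Radiation and 60.3 in Drug. Of immune cell markers CD68 had 16.2, 41.4, 39.8 and 39.3 CPM, and of endothelial markers EGFL7 had 59.9, 105, 117 and 103 CPM. Of fibroblast and pericyte markers LUM had 17.9, 18.8, 27.9 and 23.0 CPM and FAP 10.3, 13.3, 17.6 and 18.7 CPM. Of neuronal and glial markers TUBB3 had 45.5, 88.6, 111 and 109 CPM. Whether the line itself expresses these genes was not tested.

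The 16400 cells formed 4 clusters at resolution 0.5, 3 at 0.3 and 9 at 1. The largest (8035 cells, with MT1X, MMP2 and FN1 among its leading genes) held 13.1% of Control, 52.5% of Radiation, 41.2% of Drug and 68.4% of Drug_Radiation cells. A cluster of 4750 cells led by the mitosis genes KIF20A, PLK1 and CDC20 held 13.1%, 33.2%, 49.3% and 23.6%. Cells with S or G2 and M phase genes at 1% of UMIs or more were far fewer, from 1.30% of Drug_Radiation to 4.39% of Drug. Most cells of this cluster were thus outside that class. Radiation was above Control in this cluster but below it in that class (2.68% against 3.30%). A cluster of 3088 cells led by STOX1 and ATP6V0D2 held 70.7%, 13.2%, 4.97% and 4.69%, and 72.9% of its cells came from Control. The smallest had 527 cells, with AREG among its leading genes. Median depths of the clusters were 15424, 17461, 2616.5 and 8383 UMIs, so clusters followed depth as well as library.

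In cells thinned to 1000 UMIs, STOX1 was seen in 23.1% of Control cells, TET2 in 37.5% of Radiation cells, and PLXDC1 in 5.29% and TMEM108 in 4.49% of Drug_Radiation cells. Before thinning, at depths that differ between libraries, these shares were 41.8%, 80.5%, 55.4% and 55.4%. LINC00486 had 9140, 3473, 834 and 748 CPM in Control, Radiation, Drug and Drug_Radiation, but 25.7, 20.5, 19.1 and 15.1 UMIs per cell. What sets these genes apart in single libraries was not tested.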
